A study of Homo sapiens with 5 samples.

How the data were processed

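Total RNA of 5 tubular adenomas from patients with Lynch syndrome was sequenced. The labels' protocols state extraction with TRIzol and RNeasy columns and a choice of samples by RNA integrity. They do not state the depletion of ribosomal RNA, the strand setting or the read layout. The submitters' processing notes name RSEM 1.2.21, Bowtie 1.1.2 and the hg19 genome build. Per the file headers, each deposited file is an RSEM gene table with expected counts, which are estimated counts that share reads mapped to several genes between them and need not be whole. The same tables hold TPM, which per the file headers are length-adjusted transcript shares and sum to 1000000 in each library, ribosomal RNA included. They also hold FPKM, per the file headers length- and depth-scaled fragment counts, which were not used here. Transcript lengths and effective lengths, deposited in the same tables, were used only for a check of length. Genes are named by symbol with RefSeq transcripts, so values of near-identical genes are uncertain. Without a stated strand setting, genes that overlap an antisense gene cannot be told apart from it. Other settings are not given in the sources used here. No coordinates were used, since the reference at hand is of another build.

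Expected counts were rounded to whole numbers. Of 23710 genes listed, 170 were left out of all tests and lists for privacy: Y-linked genes, XIST and TSIX, HLA genes, immune receptor segments and genes with common null alleles. Counts were normalised by TMM, and filterByExpr kept 13595 genes. This filter asks for counts in every library because there is 1 group, and so removes genes absent from some adenomas. The totals of 11530026 to 20909884 expected counts set the precision, and 1 count was worth at most 0.0867 CPM. TMM factors ran from 0.854 to 1.21. For every gene, the quasi-dispersion of an intercept-only edgeR model (version 4.0.16, robust fit) was compared with its prior by the upper tail of an F distribution, with Benjamini-Hochberg adjustment. The prior had 3.93 degrees of freedom. limma 3.58.1 and DESeq2 1.42.0 were run beside it in R 4.3.3. The model has no groups, so no splits of the samples were tested.

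Gene lists for 24 programs and cell types were fixed before the data were examined, with 332 members, of which 331 were found. IL8 and KIAA1199 are the older symbols of CXCL8 and CEMIP, matched through RefSeq synonyms of another assembly, and MUC5AC was not matched. List scores are means over tested members of log2 CPM (prior count 2) centred per gene. Their SD over libraries was ranked among 10000 random lists drawn from 20 bins of mean abundance, and the top 2.5% counted as wide. Mismatch repair genes are given only as a mean and SD, and some members of that list are not reported here. Levels are medians of log2(TPM + 1), compared within a library by an exact sign-flip test, whose smallest p is 0.0625. Over-representation was tested by a one-sided Fisher's exact test over genes, which are not independent replicates. Named genes followed a rule fixed beforehand: the 2 most abundant members of each list, the 10 most abundant genes other than ribosomal protein genes, up to 20 called variable genes with a mean TPM of 10 or more (0 were called), and the 3 members with the largest SD of each wide list. Subtypes were not called, since no classifier was at hand.

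The methods were tested on simulated counts of 13595 genes with the real means and library sizes, and 200 genes planted with an extra log2 SD of 1, 2 or 4. With every gene's dispersion on the trend, edgeR recovered 13 of 67, 66 of 67 and 66 of 66 genes, with 3 false calls. With the gene-to-gene spread of dispersion seen in the data, it recovered 0 of each and made 0 false calls. A planted list of 15 genes reached the 100th percentile of spread in both simulations, and a random list the 9.10th and 69.9th. A list of 15 genes planted with independent effects of SD 4 also passed the bound, at the 100th and 99.3rd percentiles. Alternatives were another normalisation, filters, tools, pseudocounts and summaries, and leaving out each adenoma in turn.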

Results

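Gene expression was measured by RNA sequencing of total RNA in 5 tubular adenomas of the human colon from patients with Lynch syndrome. A tubular adenoma is a benign glandular tumour of the bowel lining, and Lynch syndrome is an inherited defect of DNA mismatch repair that raises the risk of colorectal cancer. The series names consensus molecular subtyping, a scheme that sorts colorectal tumours into immune, epithelial WNT and MYC, metabolic and mesenchymal classes. The labels gave 1 group, so no groups were compared. The questions asked here were which genes and gene groups the adenomas expressed, and which of them differed between the 5 adenomas. The libraries held 20909884, 18817689, 14603102, 11530026 and 13738973 expected counts in adenomas 1 to 5. A single count was worth 0.0478 to 0.0867 CPM, the count scaled to a library total of 1000000. The labels do not say whether the adenomas came from different patients. Every SD over libraries, and every p-value of a test over libraries, therefore covers only the spread between these samples, part of which can be technical. All pairs of libraries differed by more than sampling noise, so all 5 counted as separate libraries. The chi-square per degree of freedom was 15.1 for 1 pair and 77.6 to 269 for the other 9. It does not tell whether any libraries, the closest pair included, came from the same patient or the same lesion.

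The adenomas expressed a broad set of genes with the transcripts of intestinal epithelium among the most abundant. A total of 12260 genes reached 1 TPM, the length-adjusted share of transcripts scaled to 1000000, in every library, and 13027 to 14144 genes did so in each. Outside the ribosomal protein genes, FABP1, a fatty acid binding protein of enterocytes, averaged 13992 ± 6805 TPM (SD, n = 5). PHGR1, an intestinal epithelial protein, averaged 11223 ± 4224 TPM (SD, n = 5), and B2M, the light chain of major histocompatibility class I, 9819 ± 4777 TPM. The translation factor EEF1A1 stood at 8895 ± 1712 TPM, the actin-binding TMSB4X at 8638 ± 2658 TPM, TPT1 at 8391 ± 1025 TPM and the immunoglobulin joining chain IGJ at 4675 ± 2666 TPM. The ribosomal RNA precursor RNA45S5 took 26.6, 14.3, 18.2, 15.2 and 20.6% of the counts in adenomas 1 to 5. The humanin-like genes MTRNR2L2 and MTRNR2L8 averaged 39646 ± 20885 and 20398 ± 10505 TPM. These are near-identical copies of a mitochondrial RNA, so their values are uncertain. The deposited TPM and the normalised CPM scaled the libraries differently against each other. For this comparison each gene was centred over the 5 libraries on both log2 scales. The median gene's TPM value less its CPM value was then 0.33, 0.27 and 0.15 in adenomas 1, 2 and 5. In adenomas 3 and 4 it was -0.37 and -0.39. TPM values of single libraries below carry that shift.

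WNT target and crypt base genes, which mark intestinal stem cells and active WNT signalling, differed widely between the adenomas. The list score, the mean over the tested members of log2 CPM less each gene's own mean, was 1.77 and 1.56 in adenomas 1 and 2, and -1.32, -1.34 and -0.67 in adenomas 3, 4 and 5. Of the 19 tested members, 19 and 18 lay above their own mean in adenomas 1 and 2, against 0, 0 and 2 in the others. The stem cell marker LGR5 stood at 51.0, 52.0, 2.28, 1.25 and 2.09 TPM in adenomas 1 to 5. ASCL2, a stem cell transcription factor, stood at 147, 152, 5.92, 4.23 and 15.02 TPM. The WNT feedback inhibitors NKD1 and APCDD1 had SDs of 3.46 and 2.61 on the log2 CPM scale, and OLFM4, a crypt base glycoprotein, averaged 750 ± 939 TPM (SD, n = 5). Adenoma 1 held 2328 TPM of OLFM4, and the mean without it was 355 TPM. The score's SD over libraries was 1.55, where 97.5% of random lists matched for size and abundance lay under 0.25.

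Genes of the adenoma-associated list, known to be raised in colorectal adenomas, were higher in adenomas 1 and 2 too. The median member stood at a log2(TPM + 1) of 5.53 and 6.49 in adenomas 1 and 2, and at 0.68, 0.73 and 0.49 in adenomas 3, 4 and 5. The dipeptidase DPEP1 stood at 161, 132, 3.46, 5.81 and 0.89 TPM. The secreted matrix protein TGFBI averaged 249 ± 402 TPM (SD, n = 5) and 73.4 TPM without adenoma 2, and the growth factor co-receptor TDGF1 7.90 ± 9.44 TPM and 4.16 TPM without it. REG3A, an antimicrobial lectin, stood at 1660 and 1058 TPM in adenomas 1 and 2, at 5.47 and 10.9 TPM in adenomas 3 and 4, and was listed at 0 in adenoma 5. The count filter needs counts in every library and left 4 of the list's 14 members, with a score SD of 1.93. With a filter on the mean TPM, chosen after the data were seen, the 14 members had a score SD of 2.89, and all 14 lay above their own mean in adenomas 1 and 2, against 0, 2 and 1 in the others.

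Proliferation genes followed with a smaller spread. Their scores were 0.86 and 0.36 in adenomas 1 and 2, and -0.57, -0.30 and -0.36 in adenomas 3, 4 and 5, with an SD of 0.60. All 22 members lay above their own mean in adenomas 1 and 2, against 3, 5 and 4 in the others. The mitotic regulators CDC20 and TPX2 averaged 22.7 ± 20.4 and 11.1 ± 9.60 TPM (SD, n = 5), RRM2, a subunit of ribonucleotide reductase, 21.6 ± 18.4 TPM, UBE2C 52.9 ± 29.2 TPM and the replication clamp PCNA 134 ± 32.9 TPM. Without adenoma 1 the CDC20 and TPX2 means were 14.5 and 7.31 TPM. MYC targets and ribosome biogenesis genes had scores of 0.32, 0.59, -0.44, -0.35 and -0.13 and an SD of 0.44, or 0.73 on the log2(TPM + 1) scale. Among them, the nucleolar proteins NPM1 and NCL averaged 870 ± 272 and 186 ± 100.2 TPM (SD, n = 5), and RRP12, RRS1 and CAD had SDs of 0.90, 0.88 and 0.76 on the log2 CPM scale.

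Absorptive colonocyte genes, which encode ion transporters and carbonic anhydrases of mature surface cells, ran the other way. Their scores were -0.66 and -2.42 in adenomas 1 and 2, and 1.16, 1.26 and 0.66 in adenomas 3, 4 and 5, with an SD of 1.55. Of the 16 members, 4 and 0 lay above their own mean in adenomas 1 and 2, against 14, 16 and 14 in the others. Without adenoma 2 the score SD was 0.88, still outside the random range. MTRNR2L genes took 1.82, 2.60, 6.85, 7.19 and 2.20% of the counts in adenomas 1 to 5, and were thus also highest in adenomas 3 and 4. The chloride transporter SLC26A3 stood at 1081, 382, 6458, 4901 and 2204 TPM in adenomas 1 to 5, and carbonic anhydrase CA1 at 1756, 524, 5103, 4885 and 2669 TPM. GUCA2B, TMIGD1 and HSD17B2 had SDs of 2.27, 2.24 and 2.23 on the log2 CPM scale, and those of GUCA2B and TMIGD1 were 1.44 and 1.39 without adenoma 2. The goblet cell list differed less in its score, though not in each member. Its scores were 0.05, -0.42, 0.03, -0.18 and 0.52 with an SD of 0.35, at the 94.3rd percentile of random lists. The median goblet member had a log2 CPM SD of 0.68, and ZG16, SPINK4 and MUC2 had SDs of 2.27, 1.40 and 1.39. AGR2, which folds mucins, averaged 3250 ± 1317 TPM (SD, n = 5) and the mucus protein CLCA1 2920 ± 849 TPM. The goblet spread passed the 97.5% bound without adenoma 3 or without adenoma 4, with SDs of 0.40 and 0.39. The general epithelium list stood at the 86.0th percentile, with LGALS4 at 4624 ± 957 TPM (SD, n = 5). The metabolism list stood at the 91.4th percentile, with a median member SD of 0.73 on the log2 CPM scale. Its glutathione peroxidase GPX2 stood at 508 ± 366 TPM and its lactate dehydrogenase LDHA at 499.9 ± 62.1 TPM. Without adenoma 4 these lists also passed the bound, with SDs of 0.43 and 0.27. On the log2(TPM + 1) scale the goblet, epithelium and metabolism lists all passed it, with SDs of 0.53, 0.59 and 0.55. With length and GC trends removed, the goblet and metabolism lists passed it, at the 98.7th and 97.7th percentiles.

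**Figure D1:**
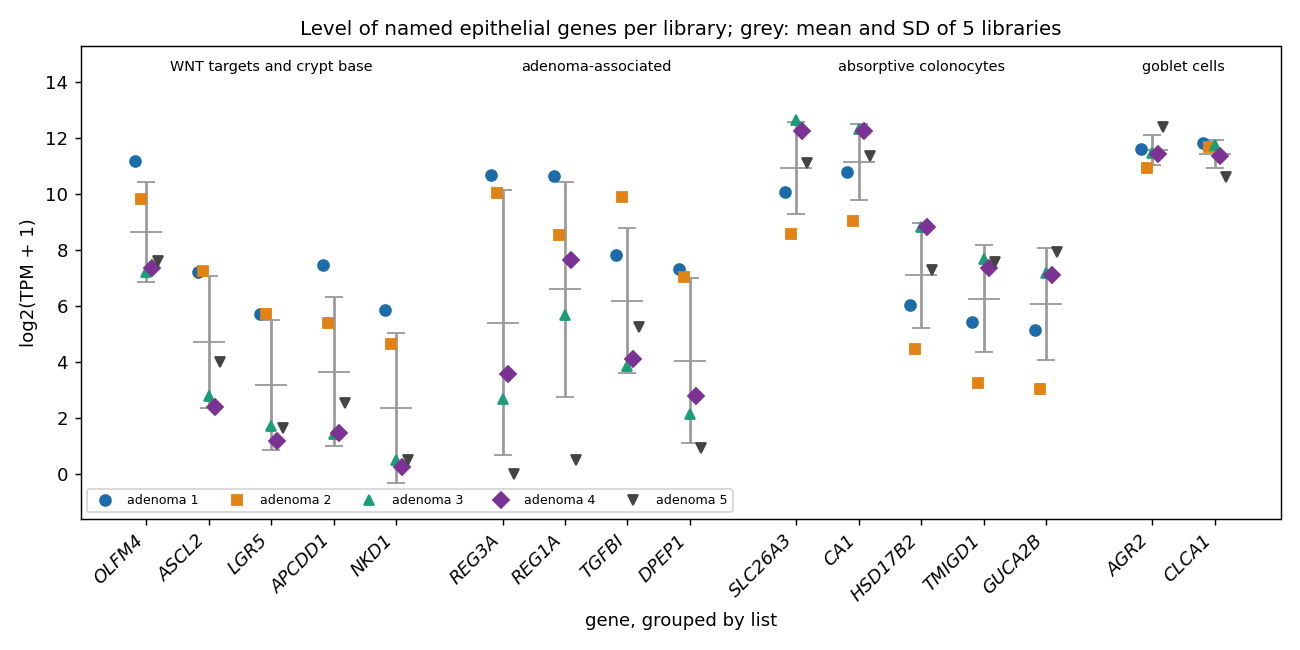
Level of named genes as log2(TPM + 1) on the vertical axis, with 1 column per gene grouped by list; each symbol is 1 adenoma library, and grey bars give the mean and SD of the 5 libraries. LGR5 stood at 51.0 and 52.0 TPM in adenomas 1 and 2 and at 2.28 TPM or less in the others, whereas SLC26A3 was lowest in adenoma 2, at 382 TPM.

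Paneth and enteroendocrine genes were highest in different adenomas, and single libraries carried much of their spread. Paneth cell genes, which encode antimicrobial peptides of the crypt base, had scores of 3.37, 1.01, -0.98, -0.92 and -2.49 in adenomas 1 to 5, with an SD of 2.25 over 3 tested members and of 1.43 without adenoma 1. The defensins DEFA5 and DEFA6, related genes, averaged 2675 ± 4626 and 689 ± 1177 TPM (SD, n = 5), with 10846 and 2755 TPM in adenoma 1 and means of 632 and 172 TPM without it. PLA2G2A, a secreted phospholipase, stood at 1416 and 1571 TPM in adenomas 1 and 5 and at 44.96 to 258 TPM in the others. Enteroendocrine genes had scores of -0.61, -3.09, 0.50, 0.59 and 2.61, with an SD of 2.08 over 3 tested members. Without adenoma 2 the SD was 1.15, but over the 8 members that the count filter then kept, so the genes scored differ. Chromogranin CHGA stood at 260 TPM and the proglucagon gene GCG at 255 TPM in adenoma 5, against 6.67 and 8.16 TPM in adenoma 2. The hormone genes INSL5 and PYY stood at 1117 and 473 TPM in adenoma 5 and at no more than 2.60 and 36.4 TPM in the others. Serrated and gastric genes had scores of 0.32, -0.29, -0.94, -0.97 and 1.89, with an SD of 1.18 over 5 tested members. With the mean TPM filter, 8 members had an SD of 1.56, and the score of adenoma 2 turned to 0.86. The trefoil peptide TFF1 averaged 441 ± 634 TPM (SD, n = 5) and 162 TPM without adenoma 5. The protease CTSE averaged 59.4 ± 66.6 TPM and 32.8 TPM without adenoma 2, and the membrane mucin MUC17 2.15 ± 3.40 TPM and 0.655 TPM without adenoma 5.

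T, NK and mast cell genes were highest in adenomas 3 and 4 on the CPM scale, the libraries with the highest MTRNR2L share, at 6.85 and 7.19% of counts. T and NK cell genes had scores of -0.74 and -0.84 in adenomas 1 and 2, 0.67 and 0.73 in adenomas 3 and 4, and 0.18 in adenoma 5. None of the 12 tested members lay above its own mean in adenoma 1 or 2, against 10, 12 and 9 in adenomas 3, 4 and 5. The granule protease GZMA stood at 7.13, 6.37, 95.6, 73.6 and 30.6 TPM in adenomas 1 to 5. CD8A averaged 6.48 ± 3.19 TPM (SD, n = 5), KLRD1 4.45 ± 2.01 TPM and the chemokine CCL5 61.3 ± 20.7 TPM. Mast cell genes stood apart most clearly, with scores of 1.47 and 1.18 in adenomas 3 and 4 and of -0.61, -1.05 and -0.98 in adenomas 1, 2 and 5. Their SD of 1.22 was 0.78 on the log2(TPM + 1) scale. The mast cell protease CPA3 stood at 127 and 76.6 TPM in adenomas 3 and 4 and at 17.4 to 21.7 TPM in the others. HPGDS and MS4A2 had SDs of 1.84 and 1.66 on the log2 CPM scale, and the tryptase gene TPSAB1, a near-identical copy of TPSB2, averaged 52.2 ± 21.6 TPM. B and plasma cell genes had scores of -0.32, -1.01, 0.14, 0.80 and 0.40. The plasma cell receptor TNFRSF17 averaged 45.4 ± 33.5 TPM (SD, n = 5), MZB1 62.0 ± 23.3 TPM and CR2 1.14 ± 0.834 TPM.

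Interferon and antigen presentation genes had scores of -0.39, -0.57, 0.38, 0.65 and -0.08. The interferon-induced chemokines CXCL9 and CXCL10 were highest in adenoma 4, at 14.5 and 25.9 TPM, and next in adenoma 3, at 7.79 and 11.8 TPM. In adenomas 1, 2 and 5 they ran from 1.49 to 2.27 TPM and from 3.98 to 5.06 TPM. IFIT1 averaged 6.72 ± 4.18 TPM (SD, n = 5) and CD74, the class II invariant chain, 568 ± 260 TPM. Myeloid genes had scores of 0.11, -0.71, 0.22, 0.35 and 0.03. Lysozyme LYZ stood at 2012 TPM in adenoma 2, where the myeloid score was lowest, and averaged 681 ± 775 TPM (SD, n = 5) with it and 348 TPM without it. C1QB averaged 136 ± 36.9 TPM, FCER1G 74.4 ± 33.8 TPM and MS4A7 13.7 ± 6.02 TPM. Immune checkpoint genes were low. Their median member had a log2(TPM + 1) of 1.11 ± 0.07 (SD, n = 5), HAVCR2 averaged 4.26 ± 0.932 TPM and LAG3 1.75 ± 0.775 TPM, and the spread stood at the 93.7th percentile. Without adenoma 2 it passed the bound, with an SD of 0.55 over 6 members chosen anew by the count filter. On the log2(TPM + 1) scale, the spreads of the interferon, T and NK, B and plasma, and myeloid lists lay inside the random range, at 0.16, 0.40, 0.42 and 0.32. The myeloid spread was also inside it without adenoma 2, at 0.14.

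Fibroblast, TGF-beta response and endothelial genes were highest in adenoma 1, and smooth muscle genes in adenoma 5. Fibroblast and mesenchymal genes had scores of 0.89, -0.33, -0.39, -0.31 and 0.14, and this spread of 0.54 was 0.24, inside the random range, without adenoma 1. Fibronectin FN1 stood at 66.6 and 16.9 TPM in adenomas 1 and 5 and at 2.11 to 3.01 TPM in the others. BGN and COL6A3 had SDs of 1.76 and 1.09 on the log2 CPM scale, the latter 0.66 without adenoma 1, and vimentin VIM and LUM averaged 129 ± 40.1 and 92.8 ± 39.7 TPM (SD, n = 5). TGF-beta response genes had scores of 0.72, 0.40, -0.65, -0.55 and 0.07. Of the 9 tested members, 8, 4, 1, 1 and 4 lay above their own mean in adenomas 1 to 5. In adenoma 2, TGFBI lay 3.45 above its own mean on the log2 CPM scale and carried much of that score. SMAD7, a feedback inhibitor, averaged 16.9 ± 6.77 TPM (SD, n = 5), LTBP2 1.96 ± 1.97 TPM and GREM1 2.31 ± 1.69 TPM. Without adenoma 1 the LTBP2 mean was 1.15 TPM and its log2 SD 0.63, against 1.03. TGFBI belongs to this list and to the adenoma-associated list. Endothelial genes had scores of 0.69, 0.33, -0.50, -0.64 and 0.13. The endothelial genes PLVAP, ENG, VWF, CDH5 and KDR averaged 22.5 ± 14.96, 14.2 ± 8.90, 2.40 ± 1.78, 2.33 ± 1.73 and 1.59 ± 1.39 TPM, and KDR averaged 1.02 TPM without adenoma 1. Smooth muscle genes had scores of 0.59, -0.73, -0.33, -0.48 and 0.95. All 10 of them lay above their own mean in adenomas 1 and 5, and DES, ACTG2 and CNN1 stood at 33.6, 38.6 and 17.4 TPM in adenoma 5. TAGLN and ACTA2 averaged 66.0 ± 45.6 and 59.2 ± 35.2 TPM (SD, n = 5).

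Markers of blood and of handling varied as well. Red blood cell genes had scores of -0.63, -1.86, 1.06, 0.29 and 1.15. The globin gene HBB averaged 83.8 ± 54.4 TPM (SD, n = 5), and the near-identical copies HBA2 and HBA1 36.6 ± 33.2 and 24.6 ± 21.1 TPM. The list SD of 1.26 was 0.82 without adenoma 2, and the HBA2 and HBA1 means were 22.8 and 15.5 TPM without adenoma 5. Immediate early and heat shock genes, which respond to stress including tissue handling, had scores of 0.02, -0.64, -0.20, 0.63 and 0.19. Their SD of 0.47 passed the bound, but not with medians over members or on the log2(TPM + 1) scale, at 0.31 and 0.43. FOS and DUSP1 were highest in adenoma 4, at 131 and 81.4 TPM, and EGR1 averaged 12.5 ± 8.00 TPM (SD, n = 5). JUNB averaged 113 ± 26.7 TPM and the chaperone DNAJB1 92.7 ± 40.3 TPM. In all, 19 of 23 lists had a spread in the top 2.5% of 10000 matched random lists, and 14 lay above every one of them. Random lists hold typical genes that do not vary together, so a group of co-expressed genes tends to pass this bound, and so did a simulated list of 15 genes that varied strongly but independently. The count describes these libraries only and does not show that the members of a list varied together.

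Across all tested genes, the first principal component held 64.0% of the variance, with scores of -41.1, -55.1, 60.1, 51.3 and -15.3 in adenomas 1 to 5.

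**Figure D2:**
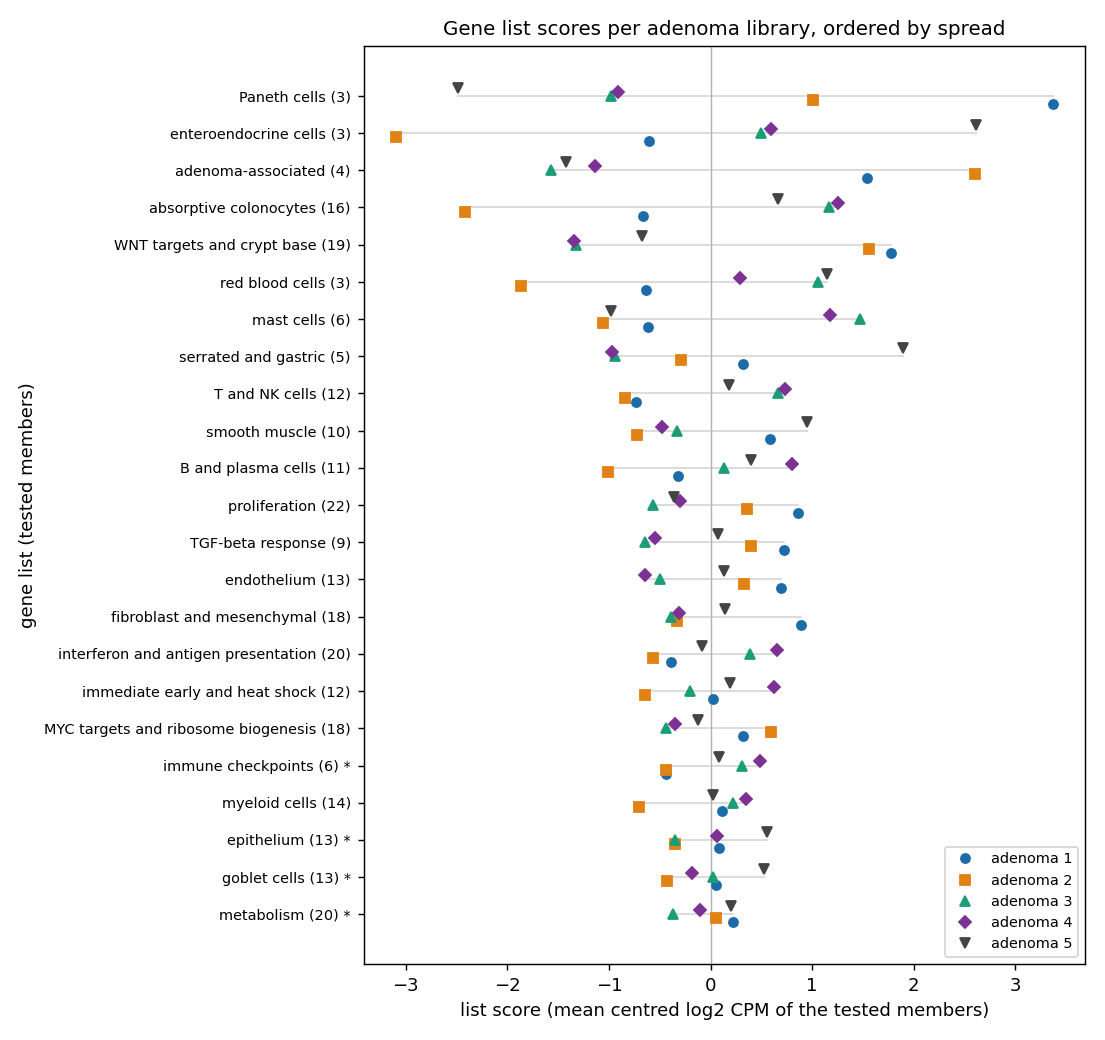
Score of each of the 23 gene lists in each library, on the horizontal axis, as the mean over tested members of log2 CPM centred on each gene's mean; each symbol is 1 adenoma, lists are ordered by the SD of their scores, the number of tested members is in brackets, and an asterisk marks the 4 lists inside the random range. WNT target scores ran from -1.34 to 1.77 and absorptive colonocyte scores from -2.42 to 1.26, with opposite signs in all 5 libraries.

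Within each library, pairs of lists were compared by the difference of their median log2(TPM + 1). This depends on the genes chosen for each list. The epithelial list exceeded the fibroblast list in all 5 adenomas, by 5.31 ± 0.65 (SD, n = 5; two-sided exact sign-flip permutation test, p = 0.0625). The WNT and crypt base list lay under the absorptive list in all 5 adenomas, with a difference of -4.63 ± 2.96 (exact sign-flip p = 0.0625). The gap ran from -0.91 in adenoma 2 to -7.34 in adenoma 3. With 5 libraries, 0.0625 is the smallest p this test can give, so none of these comparisons could pass 0.05. The goblet list differed from the absorptive list by -0.23 ± 1.69 (exact sign-flip p = 0.875), with goblet genes higher in adenomas 1, 2 and 5. The sign of that mean turned without adenoma 3 and without adenoma 4, at 0.20 and 0.21. The interferon list differed from the fibroblast list by 0.48 ± 1.30 (exact sign-flip p = 0.438) and was higher in 3 of 5 adenomas. Its mean was 0.09 without adenoma 4, 0.22 without adenoma 3 and 0.89 without adenoma 1. On the log2(CPM + 1) scale, without adjustment for transcript length, the mean goblet and interferon differences were 0.35 and -0.59, each opposite in sign. There the mean WNT and crypt base minus absorptive difference was -3.64 (exact sign-flip p = 0.125). That p is above the smallest possible, so this difference was not negative in every adenoma on that scale.

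**Figure D3:**
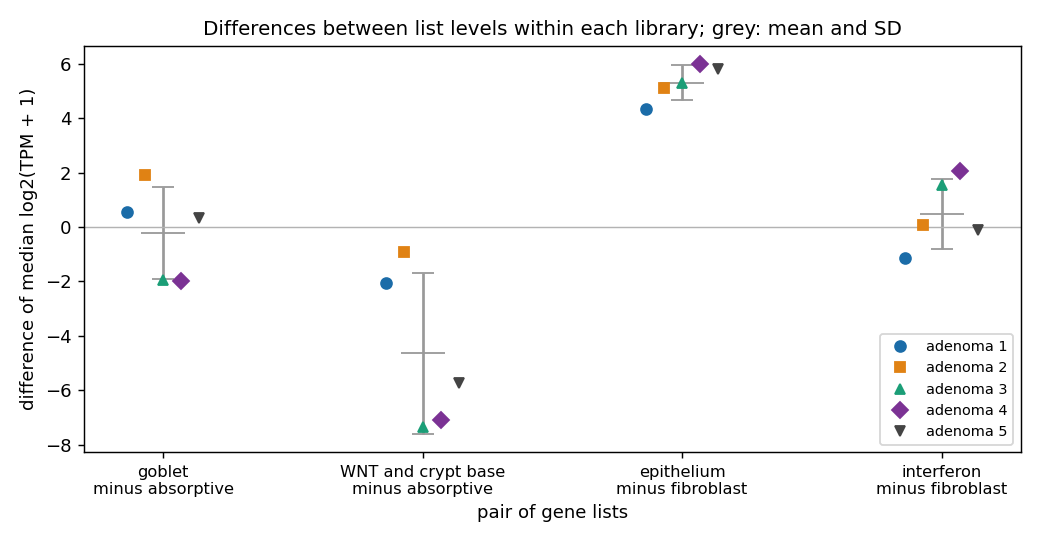
Difference of the median log2(TPM + 1) between the lists of each pair, on the vertical axis, for each adenoma; grey bars give the mean and SD of the 5 libraries. The epithelial list exceeded the fibroblast list in all 5 libraries, by 5.31 on average, and the interferon list exceeded it in 3 of 5.

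Transcripts of DNA mismatch repair genes, the pathway that is defective in Lynch syndrome, were measured at low to moderate levels. MSH3 averaged 9.06 ± 2.07 TPM, MSH6 8.30 ± 2.64 TPM and PMS1 8.27 ± 2.36 TPM (SD, n = 5). MLH3 averaged 5.64 ± 0.977 TPM, PMS2 5.58 ± 3.40 TPM and the exonuclease EXO1 2.22 ± 1.74 TPM. PMS2 shares sequence with pseudogenes, so its value is uncertain. EPCAM, an epithelial adhesion gene, averaged 1658 ± 265 TPM (SD, n = 5). Levels of single libraries are not given for these genes.

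Neither edgeR nor limma called any gene more variable than genes of its abundance, whereas DESeq2 marked 65. Of 13595 genes tested with edgeR's quasi-likelihood fit, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.943. At an unadjusted p under 0.05, edgeR called 556 genes, where 680 would be expected if every gene followed the prior. That prior was fitted to these same genes, so these counts cannot tell how much the adenomas differed. limma called 0 adjusted and 542 unadjusted. In consequence none of the lists was over-represented among called genes. The 65 dispersion outliers of DESeq2 included DEFA5, NKD1, LGR5, ASCL2, APCDD1 and TMIGD1, and 5 lists were over-represented among them by a one-sided Fisher's exact test, with adjusted p from 5.61e-09 to 0.000617. These were WNT targets (6 of 19 members), absorptive colonocytes (3 of 16), Paneth cells (3 of 3), serrated and gastric genes (3 of 5) and adenoma-associated genes (2 of 4). Fisher's test counts genes, which are not independent replicates, so its p-values do not measure a spread between samples. The count of 0 does not show that the adenomas were alike. Against counting error alone, 12663 of the 13595 genes (93.1%) varied by a chi-square test at an adjusted p under 0.05. Part of that variation can be technical. In data simulated with the observed spread of dispersions, edgeR recovered 0 of 66 genes planted with an extra SD of 4 on the log2 scale. DESeq2 recovered 61 of those 66 and also marked 114 genes that had not been planted. Those genes were simulated with dispersions spread around the trend, so they need not be false calls. With every dispersion on the trend, DESeq2 made 7 false calls. Its 65 outliers are thus not evidence of an excess over the spread of dispersions fitted to these data. That spread itself includes any genes that truly varied, so the simulation cannot show that the 65 did not vary. The median SD of log2 CPM was 0.42, and 711 genes had an SD of 1 or more.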

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

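The depth test and the length and GC test were chosen after the data were seen, and the scaling test and the goblet test after the results were seen. In 7 of 163 quantities tested, 1 library lay far from the other 4 by Dixon's test for 5 samples, where chance alone flags about 1 in 20, or 8.15. All of these were flagged on the TPM scale. TGFBI, PYY, TFF1, DEFA5 and DEFA6 were also tested as centred log2 CPM, and none was flagged there. TGFBI stood at 949 TPM in adenoma 2 and at no more than 226 TPM in the others. INSL5 stood at 1117 TPM in adenoma 5 and at no more than 2.60 TPM elsewhere, and PYY at 473 TPM in adenoma 5 and at no more than 36.4 TPM elsewhere. TFF1 stood at 1557 TPM in adenoma 5 and at no more than 318 TPM elsewhere. In adenoma 1, REG1A stood at 1590 TPM, DEFA5 at 10846 TPM and DEFA6 at 2755 TPM, where the highest of the other libraries had 369, 1883 and 564 TPM. REG1A and REG1B are close copies, and DEFA5 and DEFA6 are related genes.

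WNT target and absorptive colonocyte scores had opposite signs in all 5 adenomas. Thinned to equal totals, the spreads of both lists kept at least 99.1% of their size. CPM is already scaled to the library total, so thinning could change little beyond counting noise and does not decide on depth. Adenomas 1 and 2 had the largest totals, at 20909884 and 18817689 expected counts. Thinning cannot address other differences between libraries that go with depth, and these were not tested. Transcript length and GC content were argued against, since at least 91.0% of both spreads was kept with those trends removed. On the log2(TPM + 1) scale, which shifts the median gene by up to 0.73 between libraries, at least 81.6% of both spreads was kept. That shift is small beside the scores, so this test could not decide on library scaling. A scaling factor moves both lists of a library alike and cancels in their difference. The WNT minus absorptive difference was 2.44, 3.98, -2.48, -2.60 and -1.33 in adenomas 1 to 5, which argues against scaling as the whole cause. Different amounts of normal mucosa in the tissue sampled may contribute and cannot be told apart from a difference between adenoma cells. The goblet spread was 22.5% of the absorptive spread, but it averages members that differed among themselves and cannot decide this. The median adenoma-associated gene stood at a log2(TPM + 1) of 0.68, 0.73 and 0.49 in adenomas 3, 4 and 5. In adenomas 1 and 2 it stood at 5.53 and 6.49, which either explanation allows. Adenomas hold goblet cells of their own, and no normal mucosa was analysed here. No biological explanation was tested, because the design has 1 group.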

How the results depend on the processing

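Settings chosen after the data were seen were the mean TPM filter for the list spreads, equal depth, the length and GC correction and the removal of RNA45S5 and MTRNR2L genes. The count of 0 variable genes and of 0 over-represented lists was also found with DESeq2 size factors, no filter, a mean TPM filter, limma, a non-robust prior and without each adenoma in turn. With DESeq2 dispersion outliers they were 65 genes and 5 lists, and the simulation given with the results bears on that count. Wide lists numbered 17 to 22 under every setting tried, against 19. The lowest came with log2(TPM + 1) and the highest without adenoma 4. Single lists changed sides of the bound in 18 of 322 comparisons. With the mean TPM filter, scores near 0 changed sign for myeloid genes in adenoma 5, at -0.07, and for immediate early genes in adenoma 1, at -0.13. The goblet minus absorptive difference of -0.23 turned to 0.23 with means over members and to 0.35 on the log2(CPM + 1) scale, and ran from -0.76 to 0.21 without 1 adenoma. The interferon minus fibroblast difference of 0.48 changed to -0.59 on the log2(CPM + 1) scale, to 0.21 with members at a mean TPM of 1 or more and to 1.001 with means over members, and ran from 0.09 to 0.89 without 1 adenoma. The cause was not tested beyond the fact that CPM carries no length adjustment. Mean differences for WNT and crypt base minus absorptive genes and for epithelium minus fibroblast genes kept their sign under every setting tried. On the log2(CPM + 1) scale, the WNT and crypt base difference did not keep its sign in every adenoma. Genes detected in every library fell to 7972 at a TPM of 5 or more, as a stricter threshold must. Leaving out 1 adenoma moved the mean TPM of 14 of the 53 genes named for their level by over 1.5 times, from 225 to 2 TPM at most, for INSL5 without adenoma 5. It moved the SD of 11 of 23 lists as far. Those not given with the results were 0.47 for B and plasma cells without adenoma 2 and 0.21 for immune checkpoints without adenoma 4. They were 0.15 for metabolism without adenoma 3, and 0.22 for goblet cells and 0.25 for epithelium without adenoma 5. The count filter was run again each time, so tested members could change. Immune checkpoints had 8 members without adenoma 4, against 6 with all adenomas, so that move mixes both changes. TMM-scaled TPM moved 0 of the 53 gene means by over 1.5 times. The SDs of named variable genes moved by over 1.5 times in 22 of 336 comparisons. Depth limits low genes most, since 1 count was worth up to 0.0867 CPM.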

Other observations

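Metallothionein genes, which encode small proteins that bind zinc and copper, were not on a list fixed beforehand and were named after their values were seen. They differed widely between the adenomas. MT1G stood at 233, 101, 4878, 3848 and 452 TPM in adenomas 1 to 5, and MT1E at 165, 50.9, 1347, 1287 and 562 TPM. MT1X stood at 100.3, 66.4, 1068, 861 and 180 TPM, and MT2A at 188, 72.8, 886, 936 and 392 TPM. MT1F, MT1H and MT1M averaged 387 ± 447, 204 ± 247 and 166 ± 165 TPM (SD, n = 5). DESeq2 marked 6 of the 7 metallothionein genes tested as dispersion outliers, with the limit on that count given above. MT1 genes are near-identical copies, so their single values are uncertain.

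The test below was chosen after the result was seen. MTRNR2L2 was highest in adenomas 3 and 4, at 62804 and 62083 TPM, and varied 2.75 times between libraries, yet the ratio of MTRNR2L8 to MTRNR2L2 varied only 1.12 times, around 0.518 ± 0.0250 (SD, n = 5). Reads of 1 source shared among the copies may account for these values, and the mitochondrial RNA they resemble is a candidate source. The tables list 0 genes under mitochondrial genome names, so that source was not measured. No biological explanation was tested, because the design has 1 group.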
